A study of Mus musculus with 8 samples.

How the data were processed

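Total RNA of mouse bone marrow hematopoietic stem cells (HSCs), from mice the labels give as strain B6, was measured on 8 Agilent 1-colour expression arrays, with 1 sample per array. The groups were Nras+/+ (n = 2, the controls), NrasG12D/+ (n = 3, 1 mutant allele) and NrasG12D/G12D (n = 3, 2 mutant alleles). NrasG12D is a mutant form of the small GTPase Nras that stays in its active state. RNA was extracted with a Qiagen kit, and amplification and Cy3 labelling followed a service protocol whose steps are not given in the sources used here. The labels do not state whether each sample came from a separate animal, so p-values measure only the spread between these samples.

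The deposited scanner files hold, per the file headers, the output of Agilent Feature Extraction 10.5.1.1, also named without a version in the submitters' processing notes. The processed signal used here is an intensity on a linear scale, which per the file headers was background-subtracted and detrended within each array and was not scaled between arrays. The mean spot signal and the local background, also deposited, are intensities without correction. Other columns used were, per the file headers, flags of 0 or 1 for spots well above background, saturated spots and outlier spots. The deposited value table holds a ratio: set against the scanner values, each column equals the processed signal divided by that array's median over non-control spots, with a largest relative deviation of 1.7e-06. Each of its 8 columns has a median of 1, on a linear scale and with no centring per gene.

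Each array holds 45018 spots, of which 1639 are controls. The other 43379 spots carry 41174 probes. Of these probes, 24375 were named through their accession in a RefSeq table, 6301 through their symbol and 2419 through a synonym, while 8079 kept the name in the file. This gave 27600 gene names. Probe coordinates come from the files, which state no genome build. Spots with an outlier flag (120 to 464 per array) were set to missing, and no spot was saturated. The share of spots well above background was 36% and 30.8% in the Nras+/+ arrays, 41%, 42.4% and 28.5% in the NrasG12D/+ arrays, and 30.3%, 26% and 29.9% in the NrasG12D/G12D arrays, in order of replicate number. A surrogate value, given by Feature Extraction to signals near background, stood at 31.2% to 47.1% of the spots.

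Log2 processed signals were averaged over the spots of a probe and scaled to each array's 75th percentile. Because most spots were not well above background, the percentile was taken over the 6576 probes well above background on all 8 arrays. This probe set was chosen after the detection rates were seen and ahead of any test. A probe was tested if well above background on at least 2 arrays, and of several probes of a gene the brightest by mean signal was kept. This left 14966 genes, of which 6136 were above background on all 8 arrays. Genes were tested with limma 3.58.1 (lmFit and eBayes, two-sided, 1 spread for the 3 groups) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg over all genes tested, at a threshold of 0.05. The prior SD was 1.05 on the log2 scale with 3.83 prior degrees of freedom, beside 5 residual degrees of freedom. The number of arrays limits the precision: the median standard error of a log2 change was 0.96 for NrasG12D/+ against Nras+/+, 0.96 for NrasG12D/G12D against Nras+/+ and 0.86 between the mutant genotypes.

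Slide and genotype overlap. Slide 1 carried both Nras+/+ arrays with NrasG12D/+ replicates 1 and 2, and slide 2 carried NrasG12D/+ replicate 3 with the 3 NrasG12D/G12D arrays, each slide with 1 scan time. Values are therefore also given with the slide as a fixed block and within each slide that holds both groups. No slide holds both Nras+/+ and NrasG12D/G12D, so that comparison has no within-slide value and its blocked value rests on the NrasG12D/+ arrays alone.

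The design, the gene lists, the genes to name and all alternatives except 1 scaling were fixed before the data were examined. The probe set for the main scaling was a further exception, as stated above. In each comparison the rule named 12 genes per direction among those past the threshold with groups that do not overlap. Where fewer than 6 passed, the direction was filled to 6 with the genes of largest change at an unadjusted p under 0.01, with groups that do not overlap and an annotated symbol. It also named up to 4 members of each list past its threshold, and a fixed set of genes whatever their values. This set included Nras, Hras, Dusp6, Spry2, Spry4, Etv5, Ccnd1, Cdkn1a, Cdkn1c, Kit, Ly6a, Slamf1, Cd48 and Mki67. Some genes that the rule named are withheld and are left out of the text, though counts include them. Where the probe tested was not well above background on any array of a group, the change is given as at least N-fold. That bound sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. It allows for the background floor alone and leaves out the spread between arrays. The brighter group's mean can also include arrays not above background. An at least N-fold value is therefore no limit on the true change.

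The 28 gene lists with at least 5 tested members were tested with camera (limma, preset correlation of 0.01 between genes), which compares a list with all other genes, and adjusted over the lists of each comparison. Camera with an estimated correlation and fry stand beside it; camera compares a list with the other genes and fry with no change. The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median, no filter on dim probes or a filter on all 8 arrays, outlier spots kept, every probe by itself or the mean of a gene's probes, the deposited value table, the slide or the replicate number as a block, fits within 1 slide or with only the 2 groups compared, an intensity trend with robust variances, array weights, other thresholds, and leaving out each array in turn. Scaling over all probes was added after seeing the data. The procedure was tested on simulated data with the observed spread. Of 40 genes given a log2 change of 6, it recovered 60% for NrasG12D/+ against Nras+/+, 65% for NrasG12D/G12D against Nras+/+ and 90% between the mutant genotypes. At a log2 change of 4 these shares were 12.5%, 5% and 20%, and at a change of 1 they were 0% in each. Among unchanged genes 4, 1 and 3 were called. A list shifted by 1 was called in each comparison. The simulated genes were independent of each other and the comparisons shared 1 random draw. The result therefore overstates how well a list with correlated members is found. Other tools were data.table (version 1.17.8), statmod 1.5.0, Python 3.11.15 and matplotlib 3.10.9.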

Results

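Expression was measured in bone marrow HSCs of 3 genotypes, to compare cells with no, 1 or 2 copies of the endogenous NrasG12D allele. There were 2 Nras+/+, 3 NrasG12D/+ and 3 NrasG12D/G12D arrays. Median processed signals ranged from 3.09 to 6.75 per array. On average over the arrays, 66.5% of the HSC identity list had a probe well above background. The share was 68.1% for the B cell markers, 61.2% for the myeloid progenitor markers, 57.5% for the megakaryocyte markers, 51.9% for the T and NK cell markers, 35.6% for the monocyte and macrophage markers, 35.5% for the erythroid markers, 32.9% for the mature neutrophil markers and 30% for the mast and basophil markers. Differences between these shares were not tested. Of the sex-linked genes used as a check of sample identity, Xist had 1 of its 4 probes well above background on all 8 arrays. Ddx3y and Eif2s3y were above background on no array, Uty on 1 array and Kdm5d on 4.

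Arrays of the same genotype resembled each other about as much as arrays of different genotypes. The mean correlation across genes was 0.631 within and 0.623 between genotypes (exact one-sided permutation p = 0.275 over 560 assignments). Across genes, which are not independent replicates, NrasG12D/+ replicate 1 had the lowest mean correlation with the other arrays, 0.563, while the other 7 lay between 0.626 and 0.641. The slides did not separate the arrays either, with 0.624 within and 0.626 between slides (exact one-sided permutation p = 0.486).

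In NrasG12D/+ HSCs the clearest difference from Nras+/+ lay in genes of the cytosolic ribosomal proteins, components of the protein-making machinery. Of 22 genes tested in this list, 17 had a higher mean in NrasG12D/+ and 5 a lower one. The median log2 change was 1.40, or 1.66 above the median of all genes (camera FDR = 0.0215). With an estimated correlation the list did not pass (adjusted p = 0.875), nor with fry (adjusted p = 0.57). Named members were Rpl38, with a log2 change of 4.32 (SE 1.37), Rpl22 with 2.20 (SE 0.78) and Rpl32 with 2.13 (SE 1.21), none of which passed over all genes. The Nras+/+ arrays differed for Rpl38 with an SD of 3.79, so the size of its change depends on single control arrays. The tested probe of Rpl22 was not well above background in Nras+/+, a difference of at least 1.69-fold. The mean of the list was higher on all 3 NrasG12D/+ arrays than on both Nras+/+ arrays, but its median on NrasG12D/+ replicate 3, -0.32 relative to the array's median, was lower than on both (0.04 and 0.16). The call rested on NrasG12D/+ replicate 1: without that array the median was 0.39 (FDR = 0.812). The call was also lost without Nras+/+ replicate 1 (FDR = 0.142) or 2 (FDR = 0.0722), with quantile normalization (FDR = 0.0706), scaling to the median (FDR = 0.0809), scaling over all probes (FDR = 0.0512), array weights (FDR = 0.0752), the value table (FDR = 0.0654) and a fit of only the 2 groups compared (FDR = 0.0531). With normexp background correction the median fell to 0.45, and the call remained (FDR = 5.96e-05). The median was 1.99 with the slide as a block (FDR = 0.00498) and 1.99 within slide 1 (FDR = 0.0212).

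**Figure D1:**
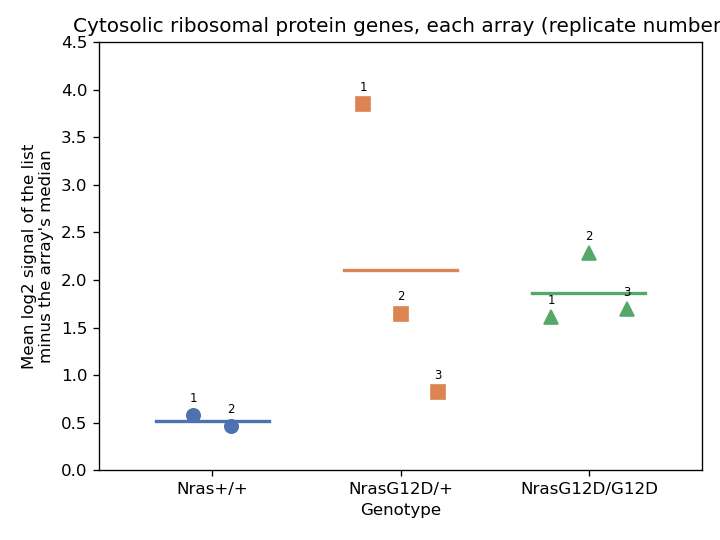
Mean log2 signal of the 22 cytosolic ribosomal protein genes tested, minus the array's median over all genes, for each array (points, with replicate numbers) and each genotype (bars, means). The Nras+/+ arrays lie at 0.58 and 0.46, NrasG12D/+ replicate 1 at 3.85, and the other mutant arrays between 0.82 and 2.28.

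No single gene passed the threshold between NrasG12D/+ and Nras+/+ in limma (0 of 14966 genes). At an unadjusted p under 0.05 there were 714 genes, 351 higher and 363 lower, against 748 by chance. The share of lower genes, 50.8%, depended on the setting: it was 33.7% with scaling to the median, 75.8% with normexp background correction, 38.4% without NrasG12D/+ replicate 1 and 74.4% without Nras+/+ replicate 2. The lowest adjusted p, 0.0648, was that of Nacc2, a transcriptional repressor of the BTB domain family. Its log2 change was -7.02 (SE 0.71). The probe was not well above background on any NrasG12D/+ array, which gives at least 48.5-fold lower, and a further Nacc2 probe was above background on only 1 array. Other genes of large negative change, none past the threshold, were Zfp787 (-8.44, SE 1.65), Igsf21 (-7.74), Pebp4 (-7.56, at least 57.2-fold lower) and Anxa11 (-7.20, at least 83-fold lower). The Nras+/+ arrays differed for Zfp787 with an SD of 4.36, and without Nras+/+ replicate 2 its change was -11.53. Among the genes that the rule named, the largest positive change was that of Dtnbp1 (7.07, at least 37.6-fold higher), a component of a complex for the biogenesis of lysosome-related organelles. Next came Rph3al (5.79), Usp21 (5.66, at least 13.5-fold higher), a ubiquitin protease, Casq1 (5.46, at least 11.5-fold higher), Meaf6 (5.43) and Sec14l4 (5.31). A further Dtnbp1 probe, above background on 7 arrays, gave -1.15. The remaining other probes of Dtnbp1, Meaf6, Zfp787 and Pebp4 were above background on no array and measure no change. All 27 genes that the rule named in this comparison had the same sign with the slide as a block and within slide 1, where Nacc2 stood at -7.11. Both fits give the same changes here, so they are not separate checks. For the genes of largest change the sign within slide 1 was fixed, since they were picked for groups that do not overlap.

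Genes named in advance for Ras signalling and stem cell identity did not pass in NrasG12D/+ either, and the median of all genes moved by -0.25. Nras itself gave -0.87 (SE 0.70), or -0.61 relative to all genes. The Ras-ERK feedback phosphatase Dusp6 gave -1.47 (SE 0.80), -1.21 relative to all genes, and the G1 cyclin Ccnd1 gave -1.0 (SE 0.90), -0.75 relative to all genes. Ly6a, the Sca-1 antigen used to sort stem cells, gave -2.32 (SE 0.89, adjusted p = 0.817), -2.06 relative to all genes, with all 3 NrasG12D/+ arrays below both controls. The groups of this comparison did not overlap for 24.9% of all genes tested, against 20% by chance. The stem cell marker Slamf1 gave -0.54 (SE 0.96) and Cd48, normally low on stem cells, -1.41 (SE 0.93). The cell cycle inhibitors Cdkn1a and Cdkn1c gave 2.08 (SE 1.78) and -0.83 (SE 0.95), the feedback inhibitor Spry2 -0.48 (SE 0.71). The ERK-responsive factor Etv5 gave 0.87 (SE 1.69) and the proliferation marker Mki67 0.92 (SE 1.32), signs that both turned with normexp background correction. The tested probes of both were not well above background in Nras+/+, which gives at least 1.41-fold higher for Mki67 and no bound for Etv5. A further Mki67 probe, above background on 3 arrays and on none of Nras+/+, gave 2.29 (at least 1.06-fold higher). Within slide 1 the changes were -1.16 for Nras, -1.97 for Dusp6, -1.61 for Ccnd1, -2.46 for Ly6a and 3.68 for Cdkn1a. Hras and Spry4 were not well above background on any array and Kit was on 1, so they were not tested.

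**Figure D2:**
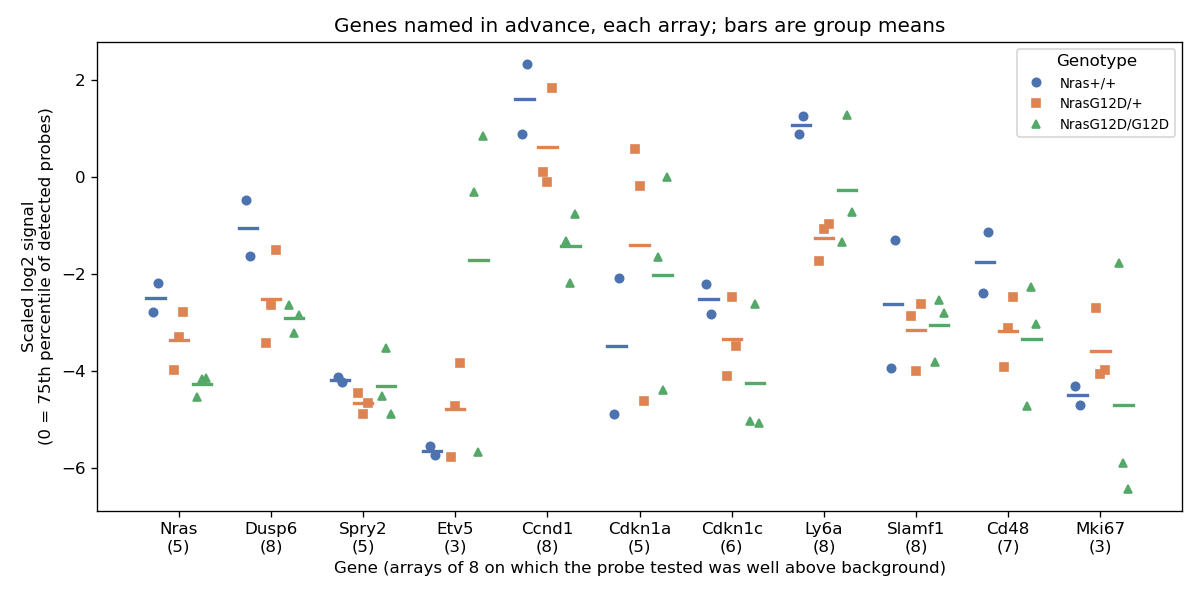
Scaled log2 signal (0 is the 75th percentile of the detected probes) of the 11 genes named in advance that were tested, for each array (points) and each genotype (bars, means), with the number of arrays on which the probe tested was well above background. Ccnd1 lies at 0.89 and 2.33 in Nras+/+ and between -2.19 and -0.77 in NrasG12D/G12D.

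The other 27 lists did not pass in NrasG12D/+ (lowest camera FDR 0.529 among them), and no gene passed when adjusted over the list alone. Among signalling lists, 5 of 13 Ras-ERK output genes, 4 of 13 Ras pathway components, 6 of 11 FOXO targets, 8 of 15 JAK-STAT targets, 4 of 7 Notch targets, 6 of 13 p53 targets, 10 of 22 interferon response genes, 6 of 15 NF-kB inflammatory genes and 5 of 12 immediate early stress genes had a higher mean than in Nras+/+. For proliferation and metabolism the counts were 9 of 18 G1/S cell cycle genes, 8 of 21 G2/M cell cycle genes, 9 of 14 quiescence regulators, 7 of 17 MYC and ribosome biogenesis genes, 10 of 18 oxidative phosphorylation genes and 7 of 14 glycolysis genes. For stem cells and their surroundings they were 6 of 19 HSC identity genes, 6 of 13 adhesion and niche genes and 1 of 9 endothelial and stromal markers. For blood lineages they were 8 of 14 myeloid progenitor, 1 of 11 mature neutrophil, 6 of 8 monocyte and macrophage, 5 of 10 erythroid, 6 of 15 megakaryocyte, 8 of 16 B cell, 4 of 12 T and NK cell and 1 of 5 mast and basophil markers. Lymphoid priming genes were higher for 2 of 13, with a median of -0.33 relative to all genes (camera FDR = 0.529). Counts of higher means are not relative to all genes, whose median moved by -0.25, so they do not give a direction by themselves. Relative to all genes the median was 0.05 for the G2/M list, 0.17 for megakaryocyte and 0.12 for mast and basophil markers. It was -0.29 for HSC identity genes, -0.42 for mature neutrophil markers and -0.61 for Ras pathway components. The median and the mean of a list differed in sign for 6 lists, and camera's direction differed from the sign of the median for 6.

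In NrasG12D/G12D HSCs the cytosolic ribosomal protein genes again lay higher than in Nras+/+. Of 22 genes, 13 had a higher mean and 9 a lower one, with a median log2 change of 0.84, or 1.28 above the median of all genes (camera FDR = 0.00879). With an estimated correlation the list did not pass (adjusted p = 0.727), nor with fry (adjusted p = 0.508). All 3 NrasG12D/G12D arrays had a list mean above both Nras+/+ arrays. Members named were Rpl22 with 1.72 (SE 0.78, at least 1.22-fold), Rps19 with 2.02 (SE 1.06) and Rpl7 with 2.10 (SE 1.26, at least 1.16-fold), none past the threshold over all genes. A further Rps19 probe, above background on 3 arrays, gave -0.46, against the 2.02 of the tested one; the remaining other probes were above background on 1 array for Rps19 and on none for Rpl7 and Rpl22. The call was lost without Nras+/+ replicate 1 (FDR = 0.0512) or 2 (FDR = 0.087), without NrasG12D/G12D replicate 2 (median 0.33, FDR = 0.0723), with quantile normalization (FDR = 0.0656), scaling over all probes (FDR = 0.0669), the value table (FDR = 0.137) and a filter on all 8 arrays (FDR = 0.127, 9 genes). The size of the change depended on the processing and on single arrays: the median fell to 0.03 with normexp background correction (FDR = 0.00588), to 0.14 with every probe by itself (FDR = 0.0481) and to 0.39 without NrasG12D/G12D replicate 3 (FDR = 0.0048). The blocked fit, with the slide as a term, gave a median of 2.68 (FDR = 0.00153). In it Rpl22 stood at 2.43, Rps19 at 4.47 and Rpl7 at 0.65.

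No gene passed between NrasG12D/G12D and Nras+/+ in limma (0 of 14966 genes), while 979 had an unadjusted p under 0.05, 196 higher and 783 lower, against 748 by chance. The share of lower genes, 80%, depended on the scaling: it was 56.6% with quantile normalization, 60.6% with scaling to the median, 43% with scaling over all probes and 34.3% in the value table. The median of all genes moved by -0.44. Nacc2 again had the lowest adjusted p, 0.0572, with a log2 change of -7.12 (SE 0.71, at least 36.2-fold lower); its other probe was above background on only 1 array. Other large negative changes were those of Pebp4 (-7.58, at least 42.7-fold lower), Arhgap8 (-7.22), Zfp787 (-7.12, SE 1.65) and Prl2b1 (-7.00, at least 26.7-fold lower). For Zfp787 the Nras+/+ arrays differed with an SD of 4.36. Among the genes that the rule named, the largest positive changes were those of Cyp2b9 (5.20, at least 16.9-fold higher), a cytochrome P450, Olfr904 (5.13) and Rab11fip5 (5.10). Next came Ndufb4 (5.0, at least 12.6-fold higher), a subunit of respiratory complex I, Cd33 (4.36, at least 4.24-fold higher), a myeloid surface lectin, and Fam220a (4.16). A further Fam220a probe, above background on 7 arrays, gave 0.15. The other probes of Cyp2b9 and Rab11fip5 were above background on 1 array and those of Pebp4, Zfp787 and Prl2b1 on none, and measure no change. With the slide as a block 26 of the 27 genes that the rule named had the same sign, the exception being Mki67. Sizes moved more for some, as for Arhgap8 (-4.02) and Olfr904 (8.89), while Nacc2 stood at -7.39. In that fit 1 gene passed, BC004015, with a log2 change of 22.77, named here after its values were seen. No slide holds both genotypes, so that value adds changes from both slides through the NrasG12D/+ arrays. With only the 2 groups compared the log2 change of BC004015 was 12.22, larger than those of the genes that the rule named.

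Among the genes named in advance, Ccnd1 had the lowest p in NrasG12D/G12D. Its log2 change was -3.04 (SE 0.90, adjusted p = 0.721), or -2.60 relative to all genes, and all 3 arrays lay below both controls. The groups of this comparison did not overlap for 28.9% of all genes tested, against 20% by chance. Dusp6 gave -1.85 (SE 0.80, adjusted p = 0.721), or -1.40 relative to all genes. The tested Nras probe, on chromosome 3 at 103195287 to 103195346 (build not stated), gave -1.79 (SE 0.70, adjusted p = 0.721), or -1.35 relative to all genes. It was not well above background on any NrasG12D/G12D array, which gives at least 3.11-fold lower, and the other 2 Nras probes were above background on no array. Etv5 gave 3.93 (SE 1.69, at least 5.28-fold higher), with 1 of the 3 arrays at the level of the controls; its other probe was above background on only 1 array. The remaining values were -1.33 (SE 0.89) for Ly6a, -1.58 (SE 0.93) for Cd48, 1.47 (SE 1.78) for Cdkn1a and -1.72 (SE 0.95) for Cdkn1c. Spry2 (-0.13), Slamf1 (-0.44) and Mki67 (-0.20) stood at 0.32, 0.007 and 0.25 relative to all genes. Their signs changed in the value table and with scaling over all probes, settings that shift all genes of an array alike. The tested Mki67 probe was not well above background in Nras+/+, so it gives no fold. The further Mki67 probe, also without an Nras+/+ array above background, gave 0.92 and no fold either. With the slide as a block the changes were -4.88 for Ccnd1, -3.36 for Dusp6, -2.66 for Nras, 2.52 for Etv5 and 6.27 for Cdkn1a. They were -2.61 for Cd48 and -1.25 for Slamf1.

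Adjusted over the list alone, 4 genes passed between NrasG12D/G12D and Nras+/+, against 0 over all genes tested. These were the Ras pathway components Ptpn11, a phosphatase that acts upstream of Ras, with -3.35 (SE 0.85, limma adjusted p over the list 0.0267), and Rasa3, a GTPase-activating protein for Ras, with -3.67 (SE 0.95, adjusted p over the list 0.0267). The others were Cd47 in the adhesion and niche list, a surface signal against phagocytosis, with -3.94 (SE 0.86, adjusted p over the list 0.0183), and Cxcl12 among the endothelial and stromal markers, a chemokine of the stem cell niche, with -4.49 (SE 1.12, adjusted p over the list 0.0281). They are named after their values were seen. The adjustment was made separately in each of the 28 lists, so a few passes can arise by chance. Their changes are not relative to all genes, which moved by -0.44. Of the Ras pathway components 2 of 13 had a higher mean than in Nras+/+, a median of -0.30 relative to all genes (camera FDR = 0.43). Ras-ERK output genes lay the other way relative to all genes, with 6 of 13 higher and a median of 0.32 (camera FDR = 0.806). Of the G2/M cell cycle genes 3 of 21 were higher (median -0.28 relative to all genes, camera FDR = 0.679), and of the G1/S cell cycle genes 7 of 18 (-0.27, camera FDR = 0.941). The fry test, which compares a list with no change and not with the other genes, gave the G1/S list an adjusted p of 0.0776, at a median of -0.71 where all genes moved by -0.44. Lymphoid priming genes were higher for 1 of 13 (-0.15, camera FDR = 0.357) and mature neutrophil markers for 2 of 11 (-0.80, camera FDR = 0.758). HSC identity genes were higher for 5 of 19 (0.08 relative to all genes, camera FDR = 0.941). Camera's direction differed from the sign of the median for 10 lists, and the median from the mean for 4.

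**Figure D3:**
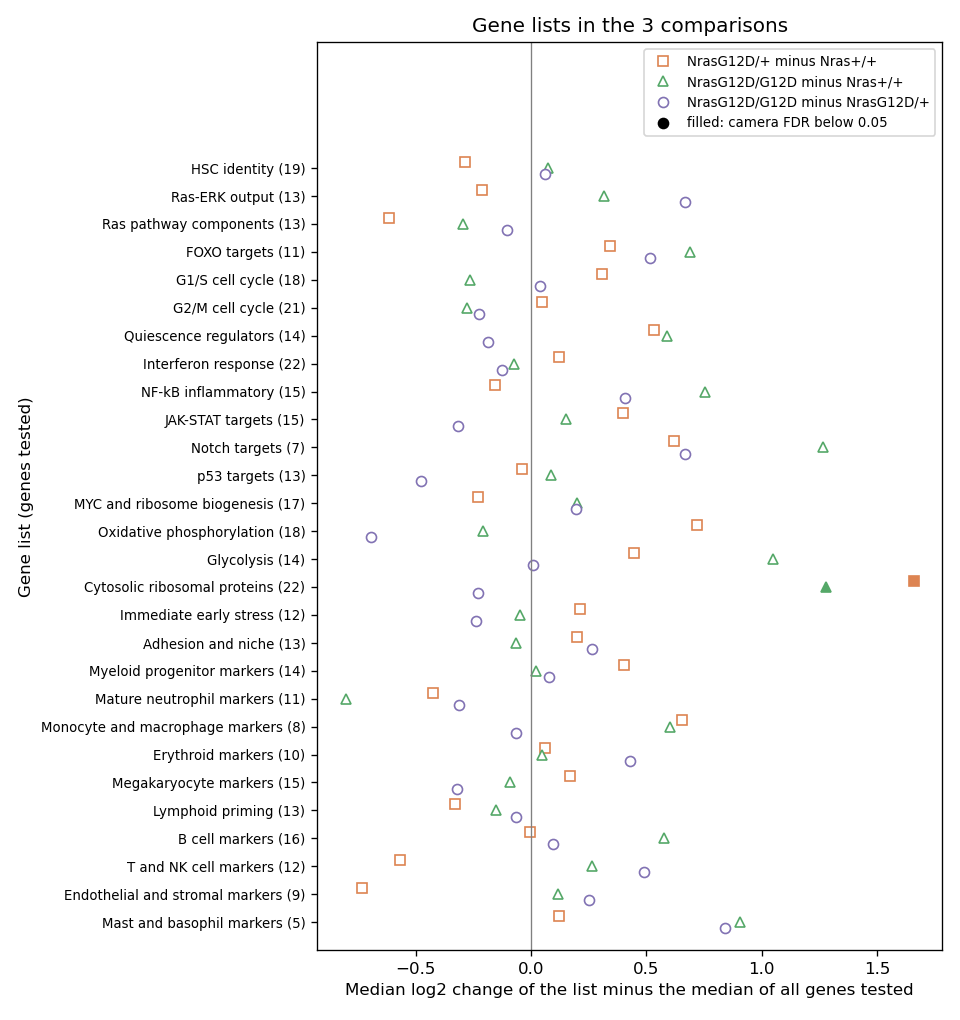
Median log2 change of each of the 28 gene lists minus the median of all genes tested, in the 3 comparisons, with the number of genes tested in parentheses. Filled symbols mark lists with a camera FDR below 0.05, which are the cytosolic ribosomal proteins at 1.66 and 1.28 in the comparisons with Nras+/+.

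Between NrasG12D/G12D and NrasG12D/+, which asks for an effect of the additional mutant allele, neither a gene nor a list passed. In limma 0 of 14966 genes passed and 889 had an unadjusted p under 0.05, 240 higher and 649 lower, against 748 by chance. The share of lower genes was 73%, but 50.5% with quantile normalization and 30.8% in the value table. Among the genes that the rule named, the largest positive changes were those of Cyp2b9 (5.21, at least 24.1-fold higher) and Anxa11 (4.84, at least 16.1-fold higher). Next came Col10a1 (4.80, SE 0.72, adjusted p = 0.495), a collagen of cartilage, Bmp1 (4.48), Dusp22 (4.14) and Ak6 (3.93, at least 4.97-fold higher). Large negative ones were those of Eef1a1 (-6.54, at least 27.6-fold lower), a translation elongation factor, Dtnbp1 (-6.11, at least 40-fold lower), Jakmip1 (-5.63), Echdc3 (-5.34, at least 9.47-fold lower) and Olfr970 (-5.33, SE 0.76, adjusted p = 0.495, at least 12.2-fold lower). Other probes above background on 5 to 7 arrays gave -1.12 for Eef1a1, 0.11 for Dtnbp1 and -0.51 for Jakmip1. The remaining other probes of these genes of largest change were above background on at most 1 array. Ccnd1 gave -2.04 (SE 0.80, adjusted p = 0.802), Etv5 3.06 (SE 1.51), Nras -0.92 (SE 0.63, not well above background on any NrasG12D/G12D array, at least 1.71-fold lower), Ly6a 0.99 (SE 0.80), Cdkn1c -0.89 (SE 0.85), Mki67 -1.12 (SE 1.18; -1.37 at its further probe) and Spry2 0.35 (SE 0.63). Dusp6 (-0.38) and Cd48 (-0.16) stood at -0.18 and 0.04 relative to all genes. Their signs changed in the value table, which shifts all genes of an array alike. Slamf1 (0.11) and Cdkn1a (-0.61) changed sign within slide 2, where NrasG12D/+ has 1 array. There the changes were -1.39 for Dusp6, -0.85 for Cd48, -1.50 for Nras, -3.26 for Ccnd1, 2.12 for Etv5, -0.71 for Mki67 and -8.55 for Jakmip1.

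For the lists of this comparison the lowest camera FDR was 0.72, the lowest adjusted p with an estimated correlation 0.856 and the lowest with fry 0.23. The cytosolic ribosomal proteins had a median of -0.43, -0.23 relative to all genes, with 7 of 22 higher (camera FDR = 0.853). Within slide 2 their median was 0.64 (FDR = 0.579). Oxidative phosphorylation genes were higher for 6 of 18 (-0.69 relative to all genes) and p53 targets for 2 of 13 (-0.48). Ras-ERK output genes were higher for 8 of 13 (0.67 relative to all genes, camera FDR = 0.72). No gene passed when adjusted over the list alone. With the slide as a block 4 genes passed, Csk, Hspb6, Jakmip1 and a transcript without a symbol, named after their values were seen, and within slide 2, where NrasG12D/+ has 1 array, 0 passed. In both fits 21 of the 23 genes that the rule named had the same sign. For the genes of largest change this was fixed, since they were picked for groups that do not overlap.

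A trend over the number of mutant alleles was found for 0 genes in limma, with a lowest adjusted p of 0.396. At an unadjusted p under 0.05 there were 1062 genes, 210 with a positive and 852 with a negative slope, against 748 by chance. The share of negative slopes was 80.2%, but 53.2% with quantile normalization, 61.2% with scaling to the median, 39.8% with scaling over all probes and 29.6% in the value table. Blocking on the slide let 1 gene pass. The changes of the mutant genotypes against Nras+/+ correlated across genes with r = 0.585 and rho = 0.581. Both share the same 2 control arrays, and simulated groups without any difference that share them gave r = 0.599. The covariance was 1.13, above the range of 0.80 to 0.91 in 100 simulations. Blocking on the slide gave r = 0.753, against 0.654 (range 0.635 to 0.672) in 100 simulations of that fit without any difference, where the changes share NrasG12D/+ arrays as well as controls. Both simulations give all arrays the same variance and leave out any correlation between arrays.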

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

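Of the settings below, only scaling over all probes was chosen after seeing the data. Between NrasG12D/+ and Nras+/+ the count of genes was 0, and it was 1 with quantile normalization, no filter on dim probes, the mean of a gene's probes, the value table, array weights or scaling over all probes, in each case Nacc2, and 1 at an adjusted p below 0.10. Between NrasG12D/G12D and Nras+/+ it was 1 with quantile normalization, no filter on dim probes, the mean of a gene's probes or array weights, again Nacc2, 1 with the slide as a fixed block or with only the 2 groups compared, in both BC004015, and 1 at an adjusted p below 0.10. Between the mutant genotypes it was 4 with the slide as a fixed block, and the trend gave 1 gene there. Leaving out 1 array moved these counts between 0 and 10, 0 and 9, and 0 and 2; the highest came without Nras+/+ replicate 2 in the first and second comparison and without NrasG12D/+ replicate 2 in the third. Without Nras+/+ replicate 2 that genotype has 1 array, assumed to vary like the other groups. The lower threshold explains the counts at 0.10, and the cause of the others was not tested. In all, 55 of 80 alternatives kept a count of 0 genes.

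The count of gene lists between NrasG12D/+ and Nras+/+ was 1, and 0 with quantile normalization, scaling to the median, the value table, only the 2 groups compared, array weights, scaling over all probes, an estimated correlation or fry. Between NrasG12D/G12D and Nras+/+ it was 1, and 0 with quantile normalization, a filter on all 8 arrays, the value table, scaling over all probes, an estimated correlation or fry. Leaving out 1 array gave 0 to 1 in both comparisons. Between the mutant genotypes it was 0 under every alternative run. The cause was not tested. The estimated correlation, 0.0533 for the ribosomal proteins, exceeds the preset 0.01, which widens the test. That test also raised p for some lists with an estimate under 0.01, so the correlation is not its only difference. For the quiescence regulators in NrasG12D/+ against Nras+/+ (estimate -0.0486) the camera p rose from 0.0859 to 0.127. The correlation of the changes against Nras+/+ was 0.585, and 0.753 with the slide as a fixed block, where the shared arrays alone give 0.654 in simulations; leaving out 1 array moved it between 0.487 and 0.710, with the lowest value without NrasG12D/+ replicate 2 and the highest without Nras+/+ replicate 1, against an SD of 0.0863 over the arrays left out. A trend and a correlation have no value within 1 slide, and a trend has none with only 2 groups.

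Of 1843 alternative values for the 77 changes of named genes, 42 had the other sign, all for genes named in advance and none past a threshold. Genes of largest change were picked for groups that do not overlap, so leaving out an array or fitting within a slide could not turn their sign. Ribosomal members were picked in the direction of their list. The count of 42 is therefore no measure of how stable signs are in general. Scaling to the median, scaling over all probes and the value table shift all genes of an array alike, and sign changes there follow that shift. In NrasG12D/G12D against Nras+/+ they moved the median of all genes from -0.44 to -0.14, 0.05 and 0.19, in that order. The cause of the other sign changes was not tested. With normexp background correction Etv5 stood at -0.30 and Mki67 at -0.16 in NrasG12D/+ against Nras+/+, and Dusp6 at 0.038, Cd48 at 0.12 and Mki67 at 0.15 between the mutant genotypes. In NrasG12D/G12D against Nras+/+, Spry2 was 0.45 with quantile normalization, 0.18 with scaling to the median, 0.51 in the value table and 0.36 with scaling over all probes. Slamf1 was 0.20 in the value table and 0.055 with scaling over all probes. Mki67 was 0.11 with scaling to the median, 0.36 with the mean of a gene's probes, 0.43 in the value table, 0.42 with the slide as a fixed block and 0.29 with scaling over all probes. Between the mutant genotypes, Dusp6 was 0.07 in the value table and Cd48 was 0.13 with quantile normalization, 0.28 in the value table and 0.16 with scaling over all probes. With the slide as a fixed block and within slide 2, Cdkn1a was 2.59 and Slamf1 -0.43. Leaving out 1 array moved Slamf1 in NrasG12D/+ against Nras+/+ between -1.86 and 0.78, Etv5 between 0.40 and 1.36 and Mki67 between 0.48 and 1.16. In NrasG12D/G12D against Nras+/+ the ranges were -0.52 to 0.16 for Spry2, -1.76 to 0.89 for Slamf1 and -1.66 to 0.67 for Mki67. Between the mutant genotypes they were -0.82 to 0.13 for Dusp6, -0.041 to 0.64 for Spry2, -2.21 to 0.58 for Cdkn1a, -0.31 to 0.48 for Slamf1, -0.70 to 0.53 for Cd48 and -2.58 to -0.25 for Mki67.

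The labels share replicate numbers between genotypes without stating a pairing. Deviations from the genotype mean correlated across genes at 0.0773 and -0.026 between Nras+/+ and NrasG12D/+ arrays of the same number, at 0.054 and 0.0356 between Nras+/+ and NrasG12D/G12D, and at 0.0345, -0.0881 and 0.0186 between the mutant genotypes, and not every array correlated best with its own number. With the replicate block 0 genes passed in each comparison, 1, 1 and 0 lists did, the trend gave 0 genes and the correlation was 0.648. In that fit Etv5 stood at -0.009 in NrasG12D/+ against Nras+/+, and Spry2 at 0.016 and Mki67 at 0.34 in NrasG12D/G12D against Nras+/+. Signal over background limits all of this: 6136 of the 14966 genes tested were above background on all 8 arrays.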

Other observations

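The tests of the slide and of near probes for the spread between arrays, of the correlation among ribosomal protein genes, of the search over all lists and of the splits of the 6 mutant arrays were chosen only after the results were seen. Further gene lists differed in their middle values without passing. In NrasG12D/G12D against Nras+/+, 9 of 14 glycolysis genes had a higher mean, with a median of 1.05 relative to all genes (camera FDR = 0.357). The same FDR belonged to 9 of 15 NF-kB inflammatory genes (0.75), 7 of 11 FOXO targets (0.69) and 7 of 14 quiescence regulators (0.59). Megakaryocyte markers were higher for 2 of 15 (-0.09, camera FDR = 0.82) and oxidative phosphorylation genes for 4 of 18 (-0.21, camera FDR = 0.941). Between the mutant genotypes 4 of 15 JAK-STAT targets and 7 of 22 interferon response genes were higher in NrasG12D/G12D, both with a fry adjusted p of 0.235 (against no change) and with camera FDRs of 0.72. Megakaryocyte markers were higher for 3 of 15 (-0.32 relative to all genes).

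No gene passed in any comparison, and arrays of the same genotype differed with a median residual SD of 1.06 on the log2 scale. For probes above background on all 8 arrays, the tables argue against noise of the spot measurement. Over 49 such probes with several spots, the SD between spots of a probe was 0.196 times that between arrays (0.18 against 0.90). Dimmer probes are not covered by this test. Removal of the slides lowered the residual SD by 4.21%. Within a genotype the slides differ only through NrasG12D/+ replicate 3, so this cannot exclude them. The tables also argue against transcript levels that vary between samples as a whole. For 457 genes with a pair of probes above background on all 8 arrays, deviations from the genotype mean correlated at only 0.0965, beside 0.0156 for probes of different genes. Changes of NrasG12D/G12D against Nras+/+ correlated at 0.122. A candidate explanation is that short stretches of a transcript were amplified or detected independently: the correlation was 0.269 (bootstrap range 0.04 to 0.46) for 68 pairs of probes with starts at most 200 bases apart and 0.0507 (5e-04 to 0.106) for 344 pairs more than 1000 bases apart, which leaves it open. Isoforms and old probe annotation were not tested.

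The cytosolic ribosomal protein genes lay higher in both mutant genotypes than in Nras+/+. A slide difference is argued against only for NrasG12D/+ replicates 1 and 2, where the list was higher within slide 1 (camera FDR = 0.0212, unadjusted 0.000759). That fit uses the preset correlation and leaves out replicate 3. Replicate 1 had a list mean of 3.85, against 1.64 for replicate 2. Over both slides the call was lost without replicate 1 (camera FDR = 0.812). Correlation among the members may account for the calls, since neither passed with an estimated correlation (the lower adjusted p was 0.727). That test cannot settle it, because it also raised p for some lists with an estimate below the preset value. The level of the 2 Nras+/+ arrays also stays open: they had the lowest list means of all choices of 2 arrays (exact one-sided permutation p = 0.0357, the smallest that 28 choices can give), but they did not have the lowest list medians (0.04 and 0.16, against -0.32 on NrasG12D/+ replicate 3), this list was picked because it stood out, and for 28 of the 28 choices some list had a standardized gap as large. For NrasG12D/G12D, slide and genotype are told apart only through 1 array, NrasG12D/+ replicate 3 (blocked median 2.68), and an effect of genotype remains among the open explanations.

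More genes were lower than higher in NrasG12D/G12D against Nras+/+ at an unadjusted p under 0.05. After quantile normalization 56.6% of such genes were lower, against 80% here, so the share depends on the scaling. That normalization gives all arrays the same distribution and removes a shared shift whatever its source. It therefore cannot tell whether the scaling caused the excess of lower genes, and the scaling stays open as an explanation. Signal near background cannot be excluded: 69.9% of the 408 brighter genes and 87.2% of the 571 dimmer ones were lower. For a slide difference the values run the other way: with the slide as a block 77.1% of 1374 such genes were lower, and on NrasG12D/+ replicate 3 the 783 lower genes lay 0.22 above replicates 1 and 2 relative to all genes, while their median change was -1.91. Both rest on replicate 3, the single array that bridges the slides, so the slide is not excluded.

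Splits of the 6 mutant arrays into 3 and 3 are too few, at 10, for a share under 0.05. For genes, 10 of the 10 splits gave a count at least as large as the real 0, and the highest other count was 58, with NrasG12D/+ replicates 1 and 3 beside NrasG12D/G12D replicate 2. Another split, NrasG12D/+ replicates 1 and 2 beside NrasG12D/G12D replicate 1, gave 21, and the remaining ones 0. These counts may reflect a structure of the samples other than genotype. On the second principal component of the 8 arrays, NrasG12D/+ replicate 2 and NrasG12D/G12D replicates 1 and 3 lay at 60, 135 and 72 and all other arrays between -70.9 and -18.7, which parts the mutant arrays as in the split with 58 genes. The component comes from the same values, so it is no independent test, and what sets these arrays apart was not tested. For lists, 10 of the 10 splits gave at least the real 0, and the highest other count was 1. At an unadjusted p under 0.05 the real split gave 889 genes and the others 539 to 1183.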
